A study of Anguilla anguilla and Anguilla rostrata with 84 samples.

How the data were processed

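Liver RNA of each fish was labelled with Cy3 and the common pool with Cy5, per the labels' protocols, and 1 fish was hybridised per array. The authors deposited a table of spot intensity values for both channels, with foreground and background columns per slide, per the file headers. These intensity values ran from 4 to 65535 and were neither background-subtracted nor normalized, per the file headers and the values. The scanner and its software are not given in the sources used here. The authors also deposited processed values per contig, which are log2 ratios of fish over pool. Recomputing these log2 values from the deposited intensities settled their scale, direction and centring. Each is the ratio of the mean background-subtracted signals of 3 spots, on the log2 scale, minus the median of its array, and the median of every array is 0. The tool behind them is not given in the sources used here.

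Of the 84 deposited processed columns, 80 were recomputed from the raw columns of the same fish to within 0.001. The columns of restricted diet replicates 2 and 3 were exchanged between the files, which leaves their group as it was. The raw columns of laboratory control replicate 5 were identical to those of high salinity replicate 4, and those of replicate 1 at 4 ug/L cadmium to those of replicate 4 at 0.4 ug/L cadmium. The processed columns of these 2 fish matched no raw column, so both fish were left out, except where the authors' processed values were used. The processed values keep ratios in which both signals lie below background, up to 306 contigs on the array of replicate 3 at 50 ng/g PCB.

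Raw intensities were corrected with normexp (offset 50), normalized by loess within each array, and averaged over 3 spots per contig in limma 3.58.1 under R 4.3.3. Linear models (lmFit, eBayes) were fitted to 992 contigs with a mean per group. Benjamini-Hochberg adjustment was made within each comparison, with a threshold of 0.05. Laboratory comparisons used 47 laboratory fish, comparisons of sites used 35 wild fish, and comparisons across these arms used all 82. Means ± SD are over fish, and SE comes from limma. Fish are separate animals, per the design text of the series. Replicate numbers only name fish and pair none, and titles give only fish identifiers.

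Contigs were named by a rule fixed at the same stage as the design and the alternatives below. They had to pass the threshold with every fish of the first group on the same side of the mean of the second, and were ranked by size. The rule also asked for a gene name. Of 992 contigs, 0 matched a name in the gene table of the reference assembly, so that condition was dropped and at most 2 increases and 2 decreases per comparison are given. Gene lists fixed beforehand were not run for the same reason.

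St Jean and Dordogne were set as baseline sites with the design, partly from background knowledge of the contamination gradient, since the labels do not rank the sites. Correlations across contigs used group mean differences. Their permutation p came from 100 regroupings of the fish labels, the real one included. Tests of counts used up to 100 splits of the same fish with seed 20240611, and Canadian against French sites was also set against all 35 splits of the 7 sites. The number of arrays limits the precision, and a contig counted as above background where the mean background-subtracted signal was above 0. The lowest numbers in both channels on 1 array were 377 at 50 ng/g PCB, 392 on the restricted diet and 599 in the control.

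The fit was tested on simulated log ratios with the spread of the real contigs and 200 changed contigs of 992. Values were drawn from a normal distribution, independently for each contig and fish. They held no array effects, no outlying fish and no differences between sites of a country. The rates below therefore need not carry over to the real arrays. For low temperature it recovered 38% of changes of 0.5 on the log2 scale, 90% of changes of 1 and 100% of changes of 2 or 3, with 9 false among 173 calls. For St Pierre against St Jean it recovered 42%, 90%, 100% and 98% of changes of 0.5, 1, 2 and 3. For Canadian against French sites it recovered 88% of changes of 0.5 and 100% of the larger ones.

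Alternatives chosen before the data were examined were median centring, no background subtraction, the authors' processed values, leaving out contigs whose mean signal lay below the 0.25 quantile, fitting only the groups compared, scaling between arrays, and leaving out each fish. Slide as a block was also chosen then, and each slide held 1 array, so it could not be fitted. Others were chosen after seeing the data. These were turning low temperature replicate 4, alone or with other settings, or leaving it out of the shared spread, a baseline of the other 8 treatments, and reference channel brightness as a covariate. Further ones were leaving out arrays with under 500 contigs above background, leaving out Garonne replicates 4 and 5, keeping the copied raw columns, and leaving out each fish in the correlations. Median centring moved the median low temperature difference over all contigs by -0.14 on the log2 scale, and no other comparison by more than 0.1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.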

Results

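Liver RNA of 84 eels was hybridised on arrays carrying 992 contigs, which are assembled transcript sequences, each printed in 3 spots. The European eel, Anguilla anguilla, supplied 49 laboratory fish and the 15 wild fish from France, while the 20 wild fish from Canada were American eels, Anguilla rostrata. Laboratory fish formed 10 groups, namely a control and 9 treatments. These were a restricted diet (2.5% of body weight), a salinity of 18 per mil, polychlorinated biphenyls (PCB) in food at 50 or 300 ng/g dry weight, and cadmium in water at 0.4 or 4 ug/L. The others were methylmercury in food at 5 ug/g dry weight, organochlorine pesticides in food at 13 ng/g dry weight, and a temperature of 13 degrees C. Wild fish came from the Canadian sites St Jean, Sud-Ouest, St Pierre and St François and the French sites Dordogne, Garonne and Gironde, chosen by the study along a contamination gradient. Each group held 5 fish, except 4 for PCB at 300 ng/g. Every value is a log2 ratio of 1 fish over a common pool of 30 wild eels from Certes, France. The files do not pair contigs with gene names, so contigs are given by identifier, with no gene function.

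After 2 arrays were left out, 4 control fish, 4 fish at 4 ug/L cadmium and 82 fish in all remained. The contigs with signal above background in both channels numbered 599 to 842 on the control arrays, 392 to 672 on the restricted diet arrays and 377 to 990 on the arrays of PCB at 50 ng/g. They numbered 939 to 985 on the low temperature arrays, 893 to 989 at St Jean and 783 to 979 at Dordogne. The median correlation between arrays was 0.428 over 3321 pairs, and 0.540 within a group. Low temperature replicate 4 correlated at -0.56 to -0.49 with the other fish of its group, which correlated at 0.41 to 0.66 with each other. All 60 pairs of arrays below -0.3 held this array. Its direction is therefore not settled, although the labels give the same dyes for every array. Counts and correlations for low temperature are given as deposited and with the sign of this array turned, and a value given once is as deposited. Larger counts of calls are given as a percentage of the 992 contigs.

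Low temperature fish differed from the control at more contigs than any other laboratory treatment did, in the fit that shared the spread of all laboratory groups. contig_11347 rose by 2.19 on the log2 scale (SE 0.31, adjusted p = 1.14e-05), from -2.69 ± 0.35 (SD, n = 4) in the control to -0.50 ± 0.24 (SD, n = 5). contig_26781 rose by 1.93 (SE 0.39, adjusted p = 0.00203). contig_35073 fell by 1.46 (SE 0.39, adjusted p = 0.0113) and contig_10692 fell by 1.31 (SE 0.37, adjusted p = 0.0175). For contig_35073 the control had the highest mean of the 17 groups (1.46), and the restricted diet (-0.10) lay lower than low temperature (0.0015). The rule for named contigs required all 5 low temperature fish to lie on the same side of the control mean. With replicate 4 turned, the differences were 2.42 for contig_11347, 1.52 for contig_26781, -1.66 for contig_35073 and -1.04 for contig_10692, and each still passed. The call for contig_10692 was lost without low temperature replicate 4 or control replicate 4, at differences of -1.24 to -1.10. In the authors' processed values the differences were 0.98 for contig_11347, 1.53 for contig_26781, -1.50 for contig_35073 and -2.02 for contig_10692, and only the last passed.

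In all, 11.8% of 992 contigs passed for low temperature, 58 higher and 59 lower, with a median size of 0.79 on the log2 scale. The sign of 91.5% of these changes was shared by every low temperature fish, among contigs that the test on the same fish had selected. With replicate 4 turned 12.0% passed, 62 contigs higher and 57 lower, and 64.7% of these also passed as deposited. Control fish carried weight here, since 4.84% passed without control replicate 4 and 7.06% without control replicate 3. Scaling between arrays left 4.33%, 26 contigs higher and 17 lower, while fitting only these 2 groups left 3.33% and no background subtraction left 7.76%. Median centring gave 8.47%, with 6.05% shared with the calls as deposited, and the authors' processed values gave 8.67%, with 3.63% shared. With replicate 4 turned as well, the shares were 5.85% without control replicate 4, 7.86% without control replicate 3, 9.48% after scaling, 9.78% for these 2 groups alone, 10.5% without background subtraction, 8.37% after median centring and 8.67% in the authors' processed values.

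**Figure D1:**
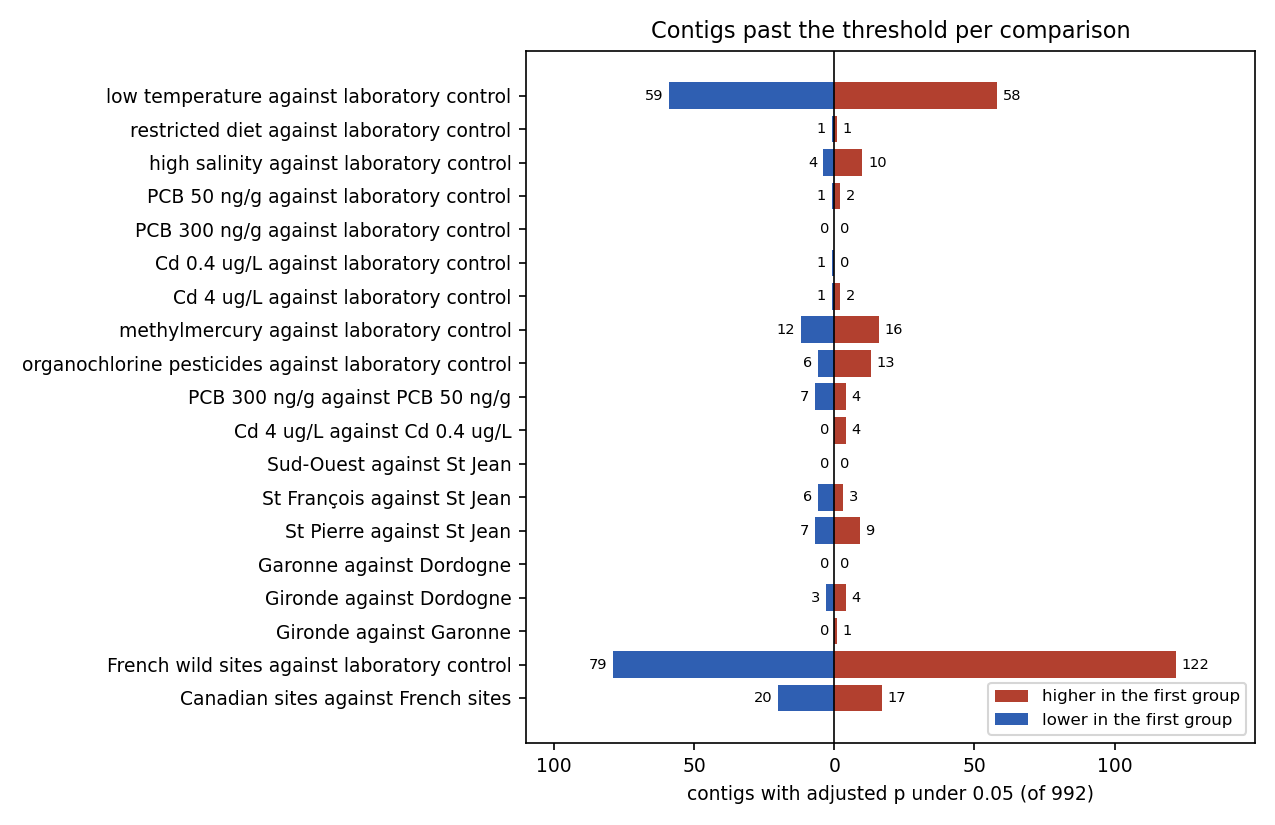
Bars give the number of contigs, of 992, with an adjusted p under 0.05 in each comparison of 2 groups or group sets, to the right where the first group was higher and to the left where it was lower. Low temperature (58 higher, 59 lower) and the French wild sites (12.3% of contigs higher, 79 lower), both against the laboratory control, have the longest bars, and low temperature holds 1 array of unsettled direction, which gives 62 higher and 57 lower when turned.

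Fish on dietary methylmercury differed from the control at 28 contigs, 16 higher and 12 lower. All 5 fish shared the sign of each difference, among contigs that the test on the same fish had selected. contig_11347 rose by 1.73 (SE 0.31, adjusted p = 0.00164) to -0.96 ± 0.21 (SD, n = 5), and contig_16092 rose by 1.53 (SE 0.36, adjusted p = 0.0172). contig_35073 fell by 1.36 (SE 0.39, adjusted p = 0.0427) and contig_17499 fell by 1.18 (SE 0.28, adjusted p = 0.0172). The call of contig_11347 held without any 1 fish. That of contig_16092 was lost without control replicate 4 (1.51), and that of contig_17499 without control replicate 4 or methylmercury replicate 1 (-1.14 to -0.89). That of contig_35073 was lost without any 1 of control replicates 1 to 4 or methylmercury replicates 1, 2, 4 and 5 (-1.45 to -1.20). The count was 2 without control replicate 4, 10 without control replicate 3 and 45 without control replicate 1, and 13, 11, 15 and 18 without methylmercury replicates 1, 2, 4 and 5 in turn. Median centring gave 14 contigs, 0 higher and 14 lower, 8 of them among the 28, and the authors' processed values gave 38, 27 higher and 11 lower, with only 3 among the 28. Fitting only these 2 groups left 2 and no background subtraction left 11. Scaling between arrays, and the mean of the other 8 treatments as baseline in place of the control, gave 0 in limma, with 12.2% and 11.3% at an unadjusted p under 0.05. Keeping the copied raw columns gave 17.

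Fish given organochlorine pesticides differed from the control at 19 contigs, 13 higher and 6 lower. contig_11347 rose by 1.60 (SE 0.31, adjusted p = 0.0061) and contig_29875 rose by 1.37 (SE 0.37, adjusted p = 0.0427). contig_19304 fell by 1.06 (SE 0.25, adjusted p = 0.0207) and contig_19263 fell by 0.92 (SE 0.19, adjusted p = 0.00632). Of the 17 groups, the control had the lowest mean for contig_29875 (-2.05) and the highest for contig_19304 (1.08). None of the 19 calls held without control replicate 4, where contig_11347 stood at 1.43 and limma called 0, with 11.5% of contigs at an unadjusted p under 0.05. Calls were also lost without control replicate 3 for contig_29875, contig_19304 and contig_19263, without pesticide replicates 1, 2, 3 or 5 for contig_29875, and without pesticide replicates 3 or 4 for contig_19304. In these fits contig_29875 stood at 1.19 to 1.43, contig_19304 at -1.03 to -0.84 and contig_19263 at -0.84 to -0.77. The count was 4 without control replicate 3, 38 and 32 without control replicates 1 and 2, and 6, 5, 5 and 11 without pesticide replicates 1, 2, 3 and 5. Median centring gave 0 in limma, with 11.3% at an unadjusted p under 0.05, scaling between arrays gave 1 higher and 0 lower, and the authors' processed values gave 6 higher and 1 lower, 0 of them among the 19. Fitting only these 2 groups left 1, no background subtraction gave 7, and the mean of the other 8 treatments as baseline gave 3, of which 2 were among the 19. Keeping the copied raw columns gave 10. High salinity fish differed from the control at 14 contigs, 10 higher and 4 lower. contig_11347 rose by 1.44 (SE 0.31, adjusted p = 0.00715) to -1.26 ± 0.14 (SD, n = 5). contig_26003 rose by 1.10 (SE 0.20, adjusted p = 0.00119), but its sample signal was above background on only 1 of 4 control arrays and its reference signal on only 2 of 5 salinity arrays. contig_18206 fell by 1.03 (SE 0.27, adjusted p = 0.0362), and contig_14090 fell by 0.68 (SE 0.14, adjusted p = 0.00542) with a sample signal above background on 2 of 5 salinity arrays. The call of contig_11347 was lost without control replicate 4 (1.26), and that of contig_18206 without control replicates 1, 3 or 4 or salinity replicates 2, 3, 4 or 5 (-1.05 to -0.88). The count was 5 without control replicate 4, 9 without control replicate 3, and 7 and 6 without salinity replicates 2 and 5. Median centring gave 2 contigs, 0 higher and 2 lower, fitting only these 2 groups 1, scaling between arrays 4 and leaving out the dimmest contigs 7. The authors' processed values gave 8, of which 2 were among the 14, the mean of the other 8 treatments as baseline gave 42, of which 9 were, and keeping the copied raw columns gave 4. The changes of contig_11347 in low temperature, methylmercury, pesticides and salinity were measured against the same 4 control fish and are not independent.

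**Figure D2:**
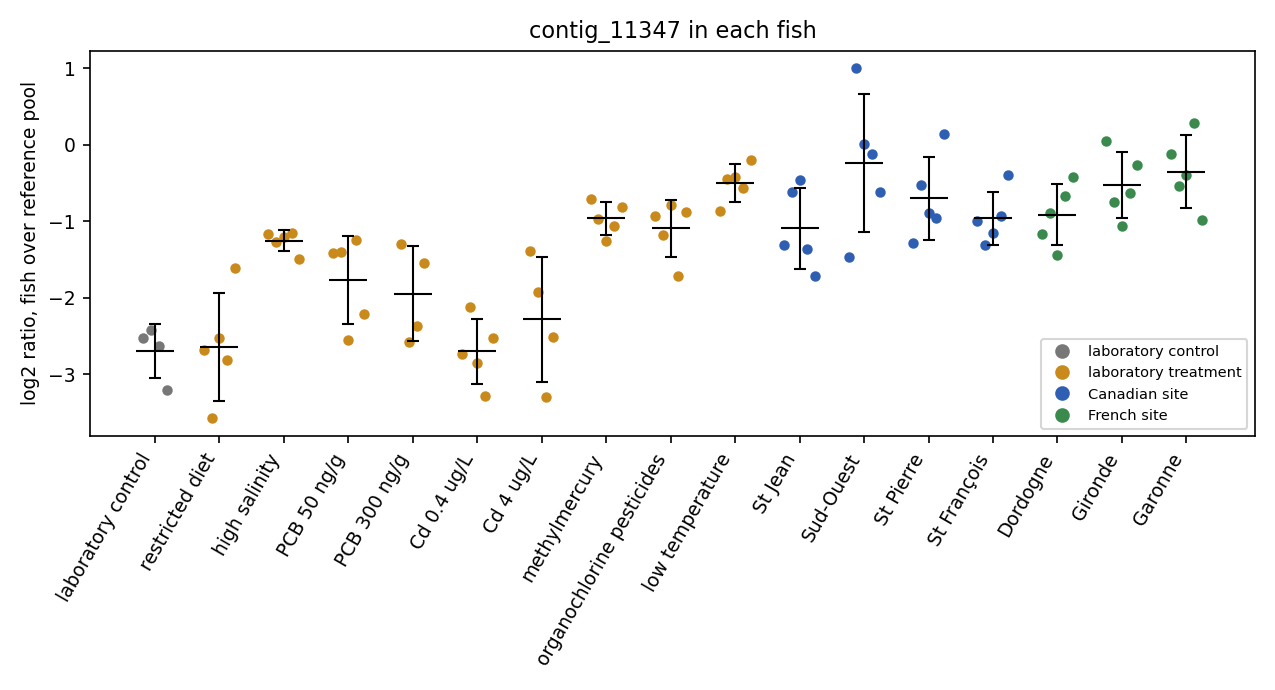
Points give the log2 ratio of contig_11347, fish over reference pool, in each of 82 fish by group, and horizontal marks with bars give the mean and SD. The control (mean -2.69), restricted diet (-2.64) and 0.4 ug/L cadmium (-2.70) groups lie lowest, and low temperature (-0.50, or -0.27 with replicate 4 turned), methylmercury (-0.96) and pesticides (-1.09) lie within or level with the range of the wild sites (-1.09 to -0.24).

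Fish on the restricted diet differed from the control at 2 contigs. contig_33173 was higher by 1.13 (SE 0.21, adjusted p = 0.00337) and contig_30632 lower by 0.94 (SE 0.21, adjusted p = 0.0189). Of the 17 groups, the control had the lowest mean for contig_33173 (-1.12) and the highest for contig_30632 (0.96). Low temperature, for example, stood at -0.15 and -0.04, so these calls are not particular to the diet. The call for contig_30632 was lost without any 1 of control replicates 2 and 3 and diet replicates 1, 3 and 4 (-0.94 to -0.83), which left a count of 1, while contig_33173 held without any 1 fish. Median centring gave 0 higher and 2 lower, neither of them among these 2, and the authors' processed values gave 4 higher and 39 lower, with 1 of these 2 among them. Scaling between arrays gave 0 in limma, with 47 at an unadjusted p under 0.05. The mean of the other 8 treatments as baseline gave 11, neither of these 2 among them, and leaving out arrays with under 500 contigs above background or keeping the copied raw columns gave 1.

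Fish given PCB at 50 ng/g differed from the control at 3 contigs. Of the 17 groups, the control had the lowest mean for contig_12003 (-1.66) and contig_30350 (-0.59) and the highest for contig_24468 (0.38). contig_12003 rose by 1.21 (SE 0.29, adjusted p = 0.0429), contig_30350 rose by 0.71 (SE 0.17, adjusted p = 0.0429) and contig_24468 fell by 0.99 (SE 0.20, adjusted p = 0.00802). The sample signal of contig_30350 was above background on 2 of 4 control arrays. The calls of contig_12003 (0.97 to 1.23) and contig_30350 (0.52 to 0.75) were lost without any 1 of control replicates 3 and 4 and PCB replicates 1, 3, 4 and 5, and that of contig_30350 also without PCB replicate 2. Without PCB replicate 1 contig_24468 stood at -0.86 and limma called 0, with 100 contigs at an unadjusted p under 0.05. The count was 19 and 22 without control replicates 1 and 2, and 1 without control replicates 3 or 4 or PCB replicates 3, 4 or 5. The authors' processed values gave 11 higher and 2 lower, none of them these 3, and no background subtraction gave 7. Median centring and fitting only these 2 groups gave 0 in limma, with 7.56% and 13.0% at an unadjusted p under 0.05, as did keeping the copied raw columns, with 13.3%. The mean of the other 8 treatments as baseline gave 9 and leaving out arrays with under 500 contigs above background 7, each with 1 of these 3. Low temperature replicate 4 left out of the shared spread gave 5 and reference brightness as a covariate 1. At 300 ng/g PCB 0 contigs passed in limma, with 12.4% at an unadjusted p under 0.05, and 1 passed when only the fish of the 2 groups were fitted or with the copied raw columns kept. Against the mean of the other 8 treatments 27 passed, 15 higher and 12 lower.

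At 0.4 ug/L cadmium contig_12784 fell by 0.81 (SE 0.18, adjusted p = 0.0433) and was the only contig to pass. It did not pass without control replicates 1, 3 or 4 or cadmium replicates 2, 3 or 5 (-0.86 to -0.65), and 2 contigs passed without control replicate 2. The authors' processed values gave 4 higher and 1 lower without this contig, and no background subtraction gave 5. Median centring, fitting only these 2 groups and scaling between arrays gave 0 in limma, with 7.46% to 8.17% at an unadjusted p under 0.05, as did keeping the copied raw columns, with 12.7%. Reference brightness as a covariate gave 2, and the mean of the other 8 treatments as baseline gave 43, 28 higher and 15 lower, this contig among them. At 4 ug/L cadmium contig_18171 rose by 1.85 (SE 0.34, adjusted p = 0.0023), to 1.84 ± 0.96 (SD, n = 4), and held without any 1 fish. Its sample signal was above background on 4 of 4 cadmium arrays and 2 of 4 control arrays. contig_11440 rose by 0.95 (SE 0.20, adjusted p = 0.0151), and its call was lost without control replicate 1 or cadmium replicate 2 (0.86 to 0.88). contig_6901 also passed, but its sample signal was above background on 0 of 4 control arrays and 1 of 4 cadmium arrays, so no size is given. Its call was lost without control replicates 1, 3 or 4 or cadmium replicates 2 or 3. The count of 3 was 6 without control replicate 2, and 8 and 5 without cadmium replicates 3 and 4, and median centring gave 1 higher and 0 lower. The authors' processed values gave 6 and fitting only these 2 groups gave 1, none of them these 3, and scaling between arrays gave 0 in limma, with 65 at an unadjusted p under 0.05. The mean of the other 8 treatments as baseline gave 61, 24 higher and 37 lower, these 3 among them, and keeping the copied raw columns gave 11.

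The doses were also compared directly. Between 300 and 50 ng/g PCB 11 contigs differed, 4 higher and 7 lower at the higher dose. contig_25366 was higher by 1.62 (SE 0.39, adjusted p = 0.0381) and contig_17942 by 1.53 (SE 0.36, adjusted p = 0.038). contig_8402 was lower by 0.94 (SE 0.24, adjusted p = 0.0404), with a sample signal above background on 3 of 5 arrays at 50 ng/g, and contig_771 by 0.86 (SE 0.20, adjusted p = 0.038). In the control, at 50 and at 300 ng/g the means were 0.65, 0.03 and 1.57 for contig_17942. They were -0.75, -0.16 and -1.10 for contig_8402 and -0.49, 0.12 and -0.74 for contig_771. The means of these contigs thus did not move in 1 direction with dose. Those of contig_25366 were -1.69, -1.74 and -0.13. Every 1 of these calls was lost without replicates 1 or 4 at 50 ng/g or replicate 2 at 300 ng/g. Further losses came without replicate 3 at 50 ng/g for contig_17942, replicates 2 or 3 at 50 ng/g and 1, 3 or 4 at 300 ng/g for contig_8402, replicate 3 at 300 ng/g for contig_17942, replicate 4 at 300 ng/g for contig_25366, and replicates 3 or 4 at 300 ng/g for contig_771. The differences then ran from 1.44 to 1.61 for contig_25366, 1.36 to 1.53 for contig_17942, -1.02 to -0.86 for contig_8402 and -0.86 to -0.70 for contig_771. Without replicate 1 at 50 ng/g or replicate 2 at 300 ng/g 0 contigs passed in limma, with 10.7% and 10.2% at an unadjusted p under 0.05. Without replicates 3 or 4 at 50 ng/g the count was 3 and 1, and without replicates 3 or 4 at 300 ng/g it was 3 and 4. Median centring, scaling between arrays and the authors' processed values gave 0 in limma, with 7.66% to 11.5% at an unadjusted p under 0.05, and no background subtraction gave 1, which was not among the 11. Low temperature replicate 4 left out of the shared spread gave 26, 12 higher and 14 lower, with all 11 among them, and reference brightness as a covariate gave 3.

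Between 4 and 0.4 ug/L cadmium 4 contigs were higher and 0 lower in limma, with 11.4% at an unadjusted p under 0.05. contig_18171 was higher at 4 ug/L by 1.56 (SE 0.32, adjusted p = 0.00877) and contig_39277 by 1.19 (SE 0.28, adjusted p = 0.0303). The call of contig_18171 was lost without replicate 5 at 4 ug/L (1.12), and that of contig_39277 without replicates 2 or 4 at 0.4 ug/L or 2 or 5 at 4 ug/L (0.79 to 1.17). The count was 11 without replicate 4 at 4 ug/L and 7 without replicate 1 at 0.4 ug/L, and the authors' processed values gave 0 higher and 1 lower. No background subtraction gave 2 and leaving out the dimmest contigs 1, and fitting only these 2 groups and scaling between arrays gave 0 in limma, with 65 and 57 at an unadjusted p under 0.05. Keeping the copied raw columns gave 1.

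Among Canadian sites, St Jean was set against the other 3. contig_9866 fell by 4.23 (SE 1.00, adjusted p = 0.0281) at St François and fell by 4.52 (SE 1.00, adjusted p = 0.0179) at St Pierre, from 1.62 ± 1.77 (SD, n = 5) at St Jean. contig_31300 rose by 2.18 (SE 0.28, adjusted p = 5.79e-06) at St François and by 1.56 (SE 0.28, adjusted p = 0.00161) at St Pierre, from -2.02 ± 0.57 (SD, n = 5). At St François contig_26357 rose by 1.88 (SE 0.29, adjusted p = 0.000102) and contig_37161 fell by 2.45 (SE 0.61, adjusted p = 0.0375). At St Pierre contig_15825 rose by 1.89 (SE 0.45, adjusted p = 0.0251) and contig_1168 fell by 2.15 (SE 0.53, adjusted p = 0.0279). These comparisons share the St Jean fish. Of the 17 groups, St Jean had the highest mean for contig_9866 (1.62) and contig_37161 (2.18), so these differences are not particular to St François or St Pierre. For contig_31300 St Jean had the lowest mean (-2.02) and St François the highest (0.16). The SD of contig_9866 within a group reached 3.22, in high salinity. The calls of contig_31300 and contig_26357 held without any 1 fish. At St François that of contig_9866 was lost without St Jean replicates 1 or 3 or St François replicates 1, 2 or 3 (-4.10 to -3.75), and that of contig_37161 without St Jean replicates 2 or 3 or any 1 St François fish (-2.59 to -2.01). At St Pierre that of contig_9866 was lost without St Jean replicate 1 or St Pierre replicate 5 (-4.04 to -3.94), and that of contig_15825 without St Jean replicates 1, 2 or 4 or St Pierre replicate 5 (1.76 to 1.89). That of contig_1168 was lost without St Jean replicates 1, 2, 3 or 5 or St Pierre replicates 4 or 5 (-2.26 to -1.39).

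St François differed from St Jean at 9 contigs, 3 higher and 6 lower, and St Pierre at 16, 9 higher and 7 lower. The St Pierre count was 2, 6, 9, 10 and 9 without St Jean replicates 1 to 5 in turn, and 10 and 6 without St Pierre replicates 4 and 5. Scaling between arrays left 4, 1 higher and 3 lower, median centring 9, the authors' processed values 7 and fitting only these 2 groups 2, while no background subtraction gave 32, 8 higher and 24 lower. The St François count was 5 without St Jean replicate 1 or St François replicates 1 or 2, and 4 without St François replicate 3 or with median centring. Sud-Ouest differed from St Jean at 0 contigs in limma, with 99 at an unadjusted p under 0.05, and 25 passed without background subtraction, 2 in the authors' processed values and 1 after scaling between arrays. A moderated F test over the 4 Canadian sites found 29 contigs, and 19 without St Jean replicate 1 or Sud-Ouest replicate 5. Median centring gave 15, the authors' processed values 16, fitting only Canadian fish 12 and scaling between arrays 18.

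Among French sites, Gironde differed from Dordogne at 7 contigs, 4 higher and 3 lower. contig_14911 rose by 2.18 (SE 0.49, adjusted p = 0.0252) and contig_18434 rose by 2.02 (SE 0.32, adjusted p = 0.000368). contig_20175 fell by 2.58 (SE 0.49, adjusted p = 0.00494) and contig_33258 fell by 1.20 (SE 0.30, adjusted p = 0.0483). contig_18434 and contig_20175 held their calls without any 1 fish. That of contig_14911 was lost without Dordogne replicates 1 to 4 or Gironde replicates 2 or 3 (1.81 to 2.24), and that of contig_33258 without Dordogne replicates 1, 3, 4 or 5 or Gironde replicates 1 to 4 (-1.31 to -1.04). The 7 became 2 or 3 without any 1 of Dordogne replicates 1 to 4 or Gironde replicates 2 to 4, and 13 without Gironde replicate 1. Median centring gave 11, 4 higher and 7 lower, of which 3 were among the 7, no background subtraction or reference brightness as a covariate left 2, and the authors' processed values gave 5 higher and 1 lower, of which 2 were among the 7.

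contig_14911 was also higher at Gironde than at Garonne, by 2.33 (SE 0.49, adjusted p = 0.0416), and no other contig passed there. Its call was lost, with 0 contigs in limma, without Gironde replicates 2 or 3 or Garonne replicates 1, 2, 3 or 5 (1.96 to 2.39), where 8.77% to 15.5% had an unadjusted p under 0.05. Median centring, no background subtraction, scaling between arrays and fitting only these 2 groups also gave 0 in limma, with 7.16% to 9.98%, as did reference brightness as a covariate, with 7.66%. The count was 3 without Gironde replicate 1, 6 without Gironde replicate 5 and 2 without Garonne replicate 4. Garonne differed from Dordogne at 0 contigs in limma, with 60 at an unadjusted p under 0.05. It differed at 2 after scaling between arrays or without Garonne replicate 2, and at 1 without Dordogne replicate 1 or in the authors' processed values. A moderated F test over the 3 French sites found contig_14911, contig_18434 and contig_20175. That count of 3 was 1 without Gironde replicate 2, 7 without Gironde replicate 1, 5 without Dordogne replicate 5 or Garonne replicate 4, and 17, these 3 among them, when only French fish were fitted.

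French wild fish differed from laboratory controls of the same species at 20.3% of the 992 contigs, with 12.3% higher and 7.96% lower and a median size of 0.60 on the log2 scale. contig_11347 rose by 2.09 (SE 0.28, adjusted p = 1.51e-07), to -0.60 ± 0.47 (SD, n = 15), and contig_8430 rose by 1.81 (SE 0.36, adjusted p = 0.000272). Both held without any 1 fish. The largest decreases under the rule for named contigs, contig_8596 at -2.07 (SE 0.48) and contig_16864 at -2.02 (SE 0.54), rested on control replicate 4. That fish had log2 ratios of 8.05 and 8.91 for these contigs, and the differences were -0.14 and 0.23 without it, both without a call. The sample signal of contig_8596 was above background on 2 of 4 control arrays. The share was 6.65% without control replicate 4 and 10.2% without control replicate 3. Median centring gave 11.9%, 41 contigs higher and 77 lower, scaling between arrays gave 5.95% and no background subtraction gave 8.97%.

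**Figure D3:**
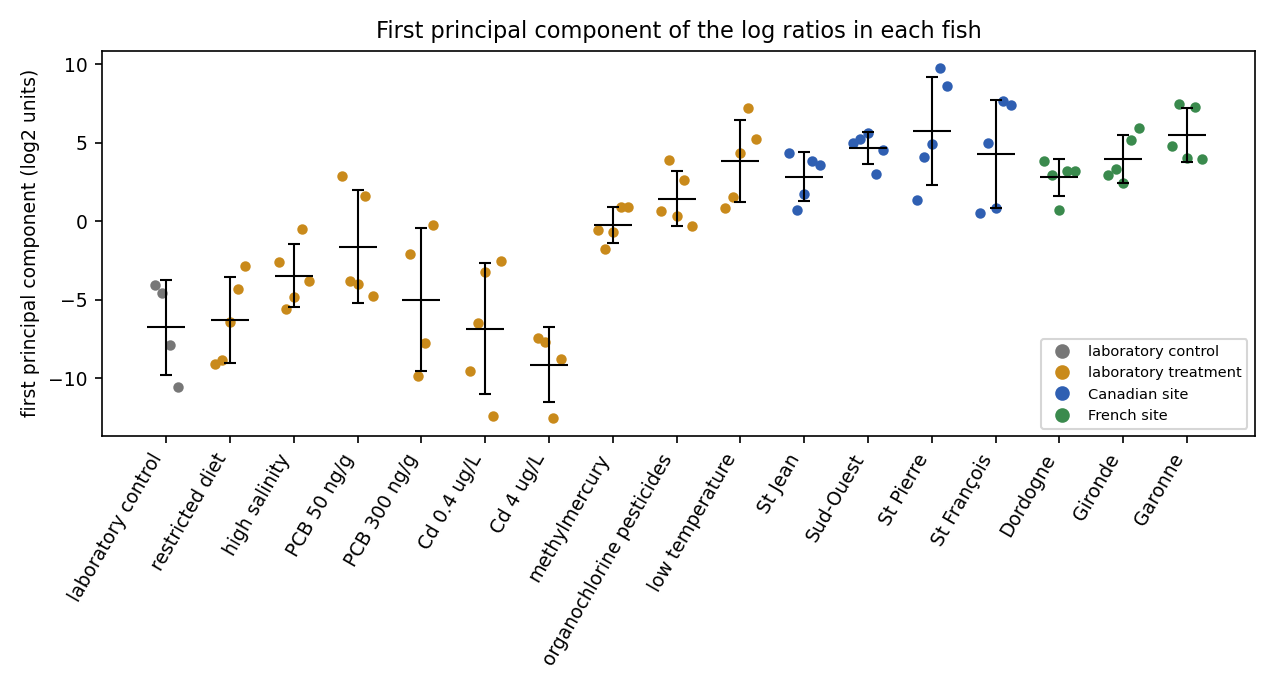
Points give the first principal component of the log2 ratios over 992 contigs, which carried 15.0% of the variance, in each of 82 fish by group, and horizontal marks with bars give the mean and SD. The 4 ug/L cadmium (mean -9.13), 0.4 ug/L cadmium (-6.84), control (-6.76) and restricted diet (-6.30) groups lie lowest, and low temperature (3.84, or 3.66 with replicate 4 turned and components refitted) lies among the wild sites (2.80 to 5.76).

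Canadian fish differed from French wild fish at 37 contigs, 17 higher and 20 lower in Canada. contig_35480 was higher by 0.64 (SE 0.11, adjusted p = 0.000102) and contig_4001 by 0.48 (SE 0.11, adjusted p = 0.0054). contig_38621 fell by 0.92 (SE 0.19, adjusted p = 0.00144) and contig_38699 fell by 0.67 (SE 0.13, adjusted p = 0.000851) relative to France. These 4 calls held without any 1 fish. The sign was shared by all 20 Canadian fish for 5 of the 37 contigs. The test rests on the spread of fish within the 7 sites, not on that between sites. Species and country cannot be told apart, and binding of American eel RNA to European eel sequences was not tested. Median centring gave 110, 93 higher and 17 lower, scaling between arrays gave 59 and the authors' processed values gave 10, sharing 20, 37 and 8 with the 37. Without Gironde replicate 4 the count was 24, and without Garonne replicates 4 and 5 it was 21.

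The series title names a response common to low temperature and chronic pollution, so the low temperature change was set against each of 5 site changes across contigs, which are not independent replicates. Pearson's r was 0.150 for Sud-Ouest, 0.0175 for St François and 0.103 for St Pierre, each against St Jean. It was 0.193 for Garonne and -0.0427 for Gironde, each against Dordogne. The labels do not rank the sites, and these 5 values depend on the choice of St Jean and Dordogne as baselines. None of the 5 passed in a two-sided permutation test over 100 regroupings of fish within a country, with permutation p from 0.07 to 0.85 and adjusted p from 0.35 to 0.85. Spearman's rho ran from -0.0381 to 0.229, with permutation p from 0.09 to 0.78 and adjusted p from 0.267 to 0.78. With low temperature replicate 4 turned, r was 0.112, 0.00216, 0.0213, 0.119 and -0.0499 in the same order, with permutation adjusted p from 0.85 to 0.98. The r for St François fell below 0 without control replicate 3, low temperature replicates 4 or 5, St Jean replicate 2, or St François replicates 4 or 5, at -0.0416 to -0.0116. Without any 1 fish r ran from 0.0880 to 0.183 for Sud-Ouest, 0.0199 to 0.166 for St Pierre and 0.113 to 0.231 for Garonne, each lowest without low temperature replicate 4, and from -0.0812 to -0.0133 for Gironde. Median centring gave 0.244, 0.0649, 0.160, -0.0245 and -0.226 in the same order of sites, no background subtraction 0.205, 0.0930, 0.164, 0.173 and 0.0165, scaling between arrays 0.0976, 0.0200, 0.0609, 0.158 and 0.0324, and the authors' processed values 0.111, 0.0436, 0.0752, 0.0595 and -0.110. None of these passed, with permutation adjusted p of at least 0.2.

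Calls shared between low temperature and a site were few. St François and low temperature shared 1 contig higher, where independent lists would share 0.175, and 0 lower, where they would share 0.357, and 1 contig moved in opposite directions. St Pierre and low temperature shared 1 higher, against 0.53, and 1 lower, against 0.416, with 0 opposite. Gironde shared 0 in either direction, against 0.234 and 0.178, with 1 opposite (2 with replicate 4 turned). With replicate 4 turned, the other shared and opposite counts were as deposited. For Sud-Ouest and Garonne limma called 0 contigs, with 99 and 60 at an unadjusted p under 0.05.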

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

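All tests of explanations in this part were chosen after the result was seen, except the test of single French sites and the split of whole sites, whose bound was set before it was run. A fish far from the others of its group was found in 17 groups of values, which is 9.77% of the groups tested, and chance alone does this in about 1 in 20 groups.

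Contigs above background in both channels numbered 857 on the array of pesticide replicate 2, where the nearest fish of its group had 961. They numbered 920 for Sud-Ouest replicate 1 (nearest 972), 783 for Dordogne replicate 3 (nearest 946) and 846 for Gironde replicate 4 (nearest 974). Dordogne replicate 3 also stood apart on the first principal component, at 0.72 against a nearest value of 2.97. Control replicate 4 stood apart for 4 contigs, with log2 ratios of 8.05 for contig_8596 (nearest 0.38), 8.91 for contig_16864 (nearest 0.12), -1.17 for contig_30350 (nearest -0.46) and 0.43 for contig_17499 (nearest 0.28). Among other laboratory fish, PCB 50 ng/g replicate 5 had -0.44 for contig_8402 (nearest -0.12). St Pierre replicate 4 had 0.93 for contig_15825 (nearest 1.10) and -2.83 for contig_1168 (nearest 0.63). Dordogne replicate 1 had -0.78 for contig_14911 (nearest -0.22) and 0.22 for contig_4001 (nearest -0.03). Gironde replicate 1 had 0.67 for contig_18434 (nearest 0.46), and Garonne replicate 1 had 1.65 for contig_38621 (nearest 0.85).

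The array of low temperature replicate 4 had a median correlation of -0.37 with all other arrays, where the nearest fish of its group had 0.41. An exchange of the deposited channel columns would give it a sample background below the reference background, but the ratio was 24.5, above the median of 2.94 on the other arrays, which ran from 0.480 to 25.8. Labelling with the opposite dyes remains a candidate explanation, since its reference column leaned more toward the sample columns of other arrays than on any other array. The difference of median rank correlations was -0.0139, where other arrays ran from -0.0668 to -0.0184. Once turned, the array correlated at 0.49 to 0.56 with its group, and no biological explanation was tested.

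Low temperature gave more contigs past the threshold than any other treatment, 11.8% of the contigs on the array. Atypical control arrays as the whole cause are argued against by the baseline of the other 8 treatments, with no control array, where 10.3% passed, against 0% to 6.15% for the other treatments taken the same way, among which methylmercury dropped from 28 contigs to 0 and pesticides from 19 to 3 (with replicate 4 turned, 11.4% against 0% to 7.96%). Brightness of the reference channel is argued against likewise, since 13.4% passed with that brightness as a covariate, against 0% to 3.13% for the other treatments (turned, 11.4% against 0% to 3.53%). Brightness of the sample channel was not tested for this count. The median sample signal was higher on every low temperature array than on any control array. Contigs above background in both channels numbered 939 to 985 at low temperature and 599 to 842 in the control, so these ranges did not overlap. A batch of arrays hybridised together was not tested and cannot be told apart from the treatment. Each slide held 1 array, so slides say nothing about batches, and which arrays were hybridised together is not known. An effect of temperature on the liver therefore remains a hypothesis, and part of the count may come from control fish, since 4.84% passed without control replicate 4 and 7.06% without control replicate 3 (turned, 5.85% and 7.86%).

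French wild fish differed from the control at 20.3% of contigs, more than any treatment did, and at 6.65% without control replicate 4 and 10.2% without control replicate 3. The number of wild fish may contribute, and the test of single sites left it open: Garonne alone gave 16.1%, above the 14.3% of low temperature in the same fit, but Gironde gave 12.7% and Dordogne 8.27%, with an SD of 3.94 percentage points between sites (with low temperature replicate 4 turned, Garonne gave 17.4% against 13.9%, with an SD of 4.39). That test was written beforehand to exclude the explanation if any site exceeded low temperature, and the excess was smaller than this spread. With the mean of the 9 treatments as baseline, 28.0% passed, and 70.1% of the calls against the control passed with the same sign (turned, 29.6% and 70.6%). This baseline holds more fish than the control, which alone can raise a count, so it cannot exclude atypical control arrays. It also averages unlike groups. Taken singly, cadmium at 4 and 0.4 ug/L gave 31.6% and 26.1%, the diet 18.5%, salinity 16.8%, and PCB at 300 and 50 ng/g 15.3% and 5.54%. Methylmercury gave 7 contigs, pesticides 3 and low temperature 1 (turned, 27). Brightness of the reference channel is argued against by the 21.9% that passed with it as a covariate, while wild origin and site cannot be separated here. Sample channel brightness was not tested here either.

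Each count was set against other splits of the same fish into groups of the same sizes. Chance is unlikely for low temperature, where 1 of 100 splits gave as many (11.8% of contigs against 6.55% in the highest other split). With replicate 4 turned it was 1 of 100, at 12.0% against 3.63%. The same applies to French wild fish against the control (1 of 100, 20.3% against 9.17%). The real split is among the 100, so 1 of 100 is the lowest share possible and does not exclude chance. Chance is also unlikely for methylmercury (1 of 100, 28 contigs against 7) and pesticides (1 of 100, 19 against 7). Likewise it is unlikely for St François (1 of 100, 9 against 3), St Pierre (1 of 100, 16 against 12) and Gironde against Dordogne (1 of 100, 7 against 2). The same holds for the F tests over Canadian sites (1 of 100, 29 against 8) and French sites (1 of 100, 3 against 1). For Canadian against French fish 1 of 100 splits of single fish gave as many (37 against 25), but fish share sites, and 3 of the 35 splits of whole sites gave as many (37 against 40), so a grouping of sites by chance is not excluded. For French wild fish against the control the test likewise covers only single fish, since their 3 sites are too few for a split of whole sites. Fewer than 5 of 100 splits also gave as many for the restricted diet (2 of 100, 2 against 2), high salinity (2 of 100, 14 against 19), PCB at 50 ng/g (4 of 100, 3 against 6) and the PCB doses (2 of 100, 11 against 36), although another split called as many contigs or more. After Benjamini-Hochberg adjustment over the 21 counts, the share was 0.021 where 1 of 100 splits gave as many, 0.0323 where 2 did and 0.06 for PCB at 50 ng/g, for which chance is then not excluded. The split of the PCB fish that called 36 contigs points to a structure of these fish, which was not tested.

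Chance is likewise not excluded for 0.4 ug/L cadmium (48 of 100, 1 contig against 11), 4 ug/L cadmium (6 of 35, 3 against 8), the cadmium doses (22 of 100, 4 against 17) or Gironde against Garonne (11 of 100, 1 against 1). Splits that called 11 contigs, among the control and 0.4 ug/L cadmium fish, and 17, among the fish of both cadmium doses, point to a structure of these fish, which was not tested. With a real count of 0 every split gives as many, so the splits say nothing about PCB at 300 ng/g (35 of 35, 0 against 3), Sud-Ouest (100 of 100, 0 against 2) or Garonne against Dordogne (100 of 100, 0 against 3). Where limma called 0 contigs, 12.4% had an unadjusted p under 0.05 for PCB at 300 ng/g, 99 contigs for Sud-Ouest and 60 for Garonne.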

How the results depend on the processing

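The settings in the next 2 paragraphs were planned, and those in the paragraph after them were chosen after the data were seen. Each value is a count of contigs past the threshold, except percentages of the 992 contigs for low temperature and French wild fish against the control, and r for correlations. Except where fewer fish or contigs entered, the cause was not tested. Of the values given for named contigs under other settings, 63.3% kept direction and call, 36.7% lost the call and 0 turned, and with 1 fish left out 77.7% kept both and 22.2% lost the call. Only contig_16864 in French wild sites against laboratory control turned, and it ran from -2.85 without control replicate 1 to 0.23 without control replicate 4. Gene lists were not run, for want of gene names, and slide as a block was not run, because each slide held 1 array. No paired analysis was possible because replicate numbers follow accession order and pair no fish. Signal over background limits arrays of PCB at 50 ng/g, the restricted diet and the control, with down to 377, 392 and 599 contigs above background in both channels. Where limma called 0 contigs, in any comparison and setting, 4.74% to 16.1% of contigs had an unadjusted p under 0.05.

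Median centring in place of loess gave 11.9% for French wild fish, 2 for high salinity, 0 for PCB at 50 ng/g, 0 for 0.4 ug/L cadmium, 1 for 4 ug/L cadmium, 14 for methylmercury, 0 for pesticides and 0 for the PCB doses. It gave 4 for St François, 9 for St Pierre, 11 for Gironde against Dordogne, 0 for Gironde against Garonne, 15 for the F test over Canadian sites and 110 for Canadian against French fish, and turned r for Garonne to -0.0245. No background subtraction gave 7.76% for low temperature, 8.97% for French wild fish, 7 for PCB at 50 ng/g, 5 for 0.4 ug/L cadmium, 11 for methylmercury, 7 for pesticides, 1 for the PCB doses and 2 for the cadmium doses. It gave 25 for Sud-Ouest, 32 for St Pierre, 2 for Gironde against Dordogne and 0 for Gironde against Garonne, and turned r for Gironde to 0.0165. Scaling between arrays gave 4.33% for low temperature, 5.95% for French wild fish, 0 for the restricted diet, 4 for high salinity, 0 for 0.4 ug/L cadmium, 0 for 4 ug/L cadmium, 0 for methylmercury and 1 for pesticides. It gave 0 for the PCB doses, 0 for the cadmium doses, 1 for Sud-Ouest, 4 for St Pierre, 2 for Garonne against Dordogne, 0 for Gironde against Garonne, 18 for the F test over Canadian sites and 59 for Canadian against French fish, and turned r for Gironde to 0.0324.

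The authors' processed values gave 43 for the restricted diet, 8 for high salinity, 13 for PCB at 50 ng/g, 5 for 0.4 ug/L cadmium, 6 for 4 ug/L cadmium, 7 for pesticides, 0 for the PCB doses and 1 for the cadmium doses. They gave 2 for Sud-Ouest, 7 for St Pierre, 1 for Garonne against Dordogne, 16 for the F test over Canadian sites and 10 for Canadian against French fish. Fitting only the fish of the groups compared, with fewer fish behind the spread, gave 3.33% for low temperature, 1 for high salinity, 0 for PCB at 50 ng/g, 1 for PCB at 300 ng/g, 0 for 0.4 ug/L cadmium, 1 for 4 ug/L cadmium, 2 for methylmercury and 1 for pesticides. It gave 0 for the cadmium doses, 2 for St Pierre, 0 for Gironde against Garonne, 12 for the F test over Canadian sites and 17 for that over French sites. Leaving out the dimmest contigs, so that fewer were tested, gave 7 for high salinity and 1 for the cadmium doses, and moved no other count by more than 1.5 times.

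Among settings chosen later, the mean of the other 8 treatments as baseline gave 11 for the restricted diet, 42 for high salinity, 9 for PCB at 50 ng/g, 27 for PCB at 300 ng/g, 43 for 0.4 ug/L cadmium, 61 for 4 ug/L cadmium, 0 for methylmercury and 3 for pesticides. Reference channel brightness as a covariate gave 1 for PCB at 50 ng/g, 2 for 0.4 ug/L cadmium, 3 for the PCB doses, 2 for Gironde against Dordogne and 0 for Gironde against Garonne. Keeping the copied raw columns as deposited gave 1 for the restricted diet, 4 for high salinity, 0 for PCB at 50 ng/g, 1 for PCB at 300 ng/g, 0 for 0.4 ug/L cadmium, 11 for 4 ug/L cadmium, 17 for methylmercury, 10 for pesticides and 1 for the cadmium doses. Leaving out arrays with under 500 contigs above background gave 1 for the restricted diet and 7 for PCB at 50 ng/g. Low temperature replicate 4 left out of the shared spread gave 5 for PCB at 50 ng/g and 26 for the PCB doses, and leaving out Garonne replicates 4 and 5 gave 21 for Canadian against French fish. Turning low temperature replicate 4 moved the low temperature count by less than 1.5 times and no correlation with a site across its threshold, and turning it with control replicate 4 left out gave 5.85%.

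With 1 fish left out in turn, low temperature ran from 4.84% without control replicate 4 to 13.6% without control replicate 1, and French wild fish from 6.65% without control replicate 4 to 20.7% without Garonne replicate 5. The restricted diet ran from 1 to 2, high salinity from 5 without control replicate 4 to 20 without salinity replicate 4, PCB at 50 ng/g from 0 without PCB replicate 1 to 22 without control replicate 2, and 0.4 ug/L cadmium from 0 to 2 without control replicate 2. Cadmium at 4 ug/L ran from 2 to 8 without cadmium replicate 3, methylmercury from 2 without control replicate 4 to 45 without control replicate 1, and pesticides from 0 without control replicate 4 to 38 without control replicate 1. The PCB doses ran from 0 to 11, and the cadmium doses from 4 to 11 without replicate 4 at 4 ug/L. St François ran from 4 without its replicate 3 to 9, St Pierre from 2 without St Jean replicate 1 to 24 without St Pierre replicate 1, and the F test over Canadian sites from 19 without St Jean replicate 1 to 32 without St Pierre replicate 4. Garonne against Dordogne ran from 0 to 2 without Garonne replicate 2, Gironde against Dordogne from 2 to 13 without Gironde replicate 1, Gironde against Garonne from 0 to 6 without Gironde replicate 5, and the F test over French sites from 1 without Gironde replicate 2 to 7 without Gironde replicate 1. Canadian against French fish ran from 24 without Gironde replicate 4 to 49 without Garonne replicate 2. The correlation of low temperature with St François ran from -0.0416 without St François replicate 4 to 0.0857 without its replicate 1. PCB at 300 ng/g and Sud-Ouest stayed at 0 in limma without any 1 fish.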

Other observations

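All tests in this part were chosen after the results were seen. French wild fish were also set against each laboratory group in the fit of all 82 fish. They differed from the control at 20.3% of the 992 contigs, from the restricted diet at 18.5%, high salinity at 16.8%, PCB at 300 ng/g at 15.3%, and cadmium at 0.4 and 4 ug/L at 26.1% and 31.6%. They differed from PCB at 50 ng/g at 5.54%, from methylmercury at 7 contigs, from organochlorine pesticides at 3 and from low temperature at 1. That contig, contig_25111, lay 1.26 lower in wild fish on the log2 scale and was chosen after its value was seen. Of the 3 contigs for pesticides, also chosen after their values were seen, contig_15239 and contig_18174 were higher in wild fish by 0.63 and 0.84, and contig_35073 fell by 1.28. With low temperature replicate 4 turned the 1 contig became 27, and with that array left out 15. Canadian fish differed from low temperature at 18 contigs, or 38 with the array turned, from pesticides at 5, from methylmercury at 41 and from the control at 21.4%. Whether these counts differ from each other was not tested.

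The mean SD of log2 ratios around the reference pool ran from 0.47 for pesticides to 0.69 at 4 ug/L cadmium among laboratory groups, with 0.68 in the control and 0.51 at low temperature. It ran from 0.45 at Dordogne to 0.58 at St Pierre among wild sites, so these ranges overlapped. Among laboratory groups it was lowest for pesticides (0.47), low temperature (0.51), methylmercury (0.53) and PCB at 50 ng/g (0.54). French wild fish differed least from these same groups, at 3, 1 (turned, 27) and 7 contigs and at 5.54% of contigs. The pool came from wild eels, and a smaller spread around it was not separated from a shift toward wild fish. The relations below were not repeated after scaling between arrays.

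A hypothesis is that low temperature moves the liver profile toward that of wild fish. Across contigs, the change of each of the 9 treatments from the control was set against the difference between wild fish and the other 8 treatments, so that no array entered both sides, which gave 18 relations. For low temperature and French fish Pearson's r was 0.547 (Spearman's rho 0.590), with an exact permutation p of 0.0238 over all regroupings of the 9 fish and an adjusted p of 0.0714. The highest other regrouping gave r = 0.534. An earlier count over 100 random draws gave a permutation p of 0.05, adjusted 0.15. The r was 0.435 for pesticides and 0.366 for methylmercury, each with an exact p of 0.0159 and an adjusted p of 0.0571. For Canadian fish r was 0.508 for low temperature and 0.506 for pesticides, each with an exact p of 0.00794, and 0.332 for methylmercury with an exact p of 0.0159, all with an adjusted p of 0.0571. The remaining relations ran from -0.0834 to 0.292 for French fish and from -0.106 to 0.30 for Canadian fish. No relation passed after adjustment by Pearson's r. By Spearman's rho 3 relations reached an adjusted exact p of 0.0476, methylmercury with French fish and low temperature and pesticides with Canadian fish. With replicate 4 turned, r was 0.487 (exact p = 0.0238), below the highest regrouping of 0.495, and it was 0.480 (exact p = 0.0286) with that array left out. The hypothesis may hold, but these data leave it open, and pesticides and methylmercury show the same direction. A batch of arrays hybridised together cannot be told apart from the treatment here either. In the order of deposit, methylmercury, pesticides and low temperature come last among laboratory groups, next to the wild fish. Their mean first principal components were -0.23, 1.45 and 3.84, against -9.13 to -1.61 in the other laboratory groups. Whether hybridisation followed that order is not known.

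The calls of low temperature and of French wild fish, both against the same control fish, overlapped. They shared 46 contigs higher and 39 lower, where independent lists would share 7.13 and 4.70, with 0 in opposite directions. Lists that share control fish are not independent, and shared calls were not simulated. With replicate 4 turned they shared 44 and 35, with 0 opposite. Across contigs r was 0.855, where 100 simulations with shared controls and no effect gave a mean of 0.661, and the covariance was 0.174 against a simulated 0.0383. The simulations drew values independently, with the same spread per contig in every group and no array effects or outlying fish. They may therefore understate what shared control fish add. With the controls split, so that no control fish entered both comparisons, r was 0.42 to 0.48 and the mean covariance 0.113, which argues against shared control fish as the whole cause. Turning replicate 4 gave an r of 0.803 against a simulated 0.661, the covariance 0.165 against 0.0365, and with split controls r was 0.34 to 0.47 and the mean covariance 0.104. What all control arrays have in common, such as a batch, enters both comparisons and stays open.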
